A study of Homo sapiens with 6 samples.

How the data were processed

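RNA from HCT116 cells treated for 18 h with EI-52 (3 samples) or DMSO (3 samples) was labelled with biotin and measured on 1 Affymetrix array per sample, per the labels' protocols. The deposited values are log2 signals made with RMA by the authors, per the submitters' processing notes, which name no version. The array type, the probe set definition file and the software were not given in the sources used here. Values ran from 1.74 to 14.27, the range of log2 signals, and were used as deposited, with no further scaling in the main analysis. Probe set identifiers are Entrez gene numbers, so each gene had 1 probe set.

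Of 19425 probe sets, 62 controls were left out and 19363 were tested. No filter on signal was applied. Symbols and bands came from the authors' annotation, and 1556 symbols were replaced by newer ones from the human RefSeq table through the Entrez number. No genome build is stated for the bands. Of the tested probe sets, 16964 were protein-coding, 2021 were ncRNA and 17 had no symbol, of which 2 had annotation lines that were emptied for this work. Those 2 stayed in every test and were not named. ATF4, which the rule for named genes lists, was not analysed here.

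The 3 EI-52 arrays were compared with the 3 DMSO arrays by limma (lmFit and eBayes, without trend or robust options). Tests were two-sided with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The log2 fold change is EI-52 minus DMSO. Precision depends on the spread between arrays. The median standard error of a log2 fold change was 0.064, with 4 residual and 2.86 prior degrees of freedom, and the smallest called absolute log2 fold change was 0.33. Spreads of signal are SDs over 3 arrays, and errors of log2 fold changes are limma's moderated SEs. A probe set's groups were called non-overlapping where every EI-52 value lay on the same side of every DMSO value.

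Shifts of 37 gene lists, each with at least 5 measured members, were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists were integrated stress response, amino acid synthesis and transport, cytosolic tRNA synthetases, eIF2 kinases and translation control, ER chaperones and ER-associated degradation, heat shock proteins, NRF2 targets, metallothioneins and zinc export, p53 targets, ERK transcriptional output, immediate early genes, RAS-ERK and TLR-MYD88 pathway components, NF-kB targets and chemokines, interferon-stimulated genes, antigen processing and presentation, danger signals and immune ligands, death receptor signalling, BCL2 family, DNA replication, mitosis, DNA repair, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, autophagy and lysosome, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, mitochondrial chaperones and proteases, sphingolipid metabolism, WNT targets, intestinal epithelial identity, fibroblast markers, leukocyte and blood cell markers, endothelial markers, housekeeping genes. In each list the members past the threshold over all genes were counted, and again with p-values adjusted over the list alone.

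The lists, tests, alternatives and the rule for named genes were chosen before the data were examined. The rule named the 10 largest rises and the 10 largest falls among called, non-overlapping probe sets of named protein-coding genes. It also named up to 4 called members of each list, or the 2 with the smallest p where none was called, and always a fixed few, among them MAPK3, MYD88, DUSP6, MYC, ATF4, DDIT3, HSPA5 and CDKN1A. Only 2 probe sets fell, so both are named. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen.

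Alternatives were centring on the array median, cyclic loess, quantile normalization, centring on the housekeeping list, a filter at the median signal, an intensity trend or a robust prior, array weights, the replicate number as a block, leaving out each array, stricter thresholds, and other set tests. The analysis was tested on simulated data for the comparison of EI-52 with DMSO, with 19363 probe sets and 50 changed at each size. It called 32% of those changed 1.25-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 12 of the 169 called were unchanged. Camera found the raised list and 0 others of 37. Noise was drawn separately for each probe set, so this run could not check camera's calls where genes of a list vary together. In the data the estimated inter-gene correlation was 0.35 for cholesterol synthesis, 0.41 for DNA replication and −0.034 for ERK transcriptional output. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.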

Results

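Gene expression was measured in HCT116, an established line of human colorectal carcinoma cells, after 18 h with the compound EI-52 or with its solvent DMSO. Each treatment had 3 samples, each run on 1 Affymetrix array. The labels give 2 doses for the same samples, 8 µM in the treatment protocol and 6 µM in the design text, so both are stated here. EI-52 is known from work on the contact between the kinase ERK and the adaptor MYD88, and the comparison asked which transcripts differed between treated and vehicle cells. The deposited RMA values covered 19363 non-control probe sets, 1 per gene, on a log2 scale. Array medians lay between 6.98 and 7.05, and correlations across genes between any pair of arrays lay between 0.9963 and 0.9979. Between 2.10% and 2.77% of values were identical in any pair of arrays, so no array was a copy of another.

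Of 22 measured genes of cholesterol synthesis, 17 were higher in EI-52 than in DMSO. So were SCD, ELOVL6 and FADS1, which desaturate or elongate fatty acids, while the sterol exporter gene ABCA1 was lower. As lists, cholesterol and fatty acid synthesis passed camera's threshold, each with an adjusted p = 0.0719 with an estimated correlation. HMGCS1, an early enzyme of the pathway, was 2.66-fold higher, with a log2 fold change of 1.41 ± 0.097 (SE, n = 3 per group). INSIG1, a regulator of the pathway, was 2.60-fold higher at 1.38 ± 0.076. The chemokine genes CXCL8, CCL20, CXCL1 and CXCL2 had higher signals in EI-52 replicates 1 and 2 than in replicate 3, and none of them passed the adjusted threshold. As a list, DNA replication genes were slightly lower, with a median log2 fold change of −0.14 over 32 genes (camera adjusted p = 4.16e-13, and adjusted p = 0.391 with an estimated correlation).

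By limma with Benjamini-Hochberg adjustment, 43 of the 19363 probe sets differed at an adjusted p under 0.05, 41 of them higher and 2 lower in EI-52. All 43 had groups that did not overlap, as did 16.7% of all probe sets, where chance gives 10%. Among the 43, 10 rose at least 2-fold, against 19 at least 2-fold without EI-52 replicate 3 and 4 past limma's treat test against 1.5-fold. None of the 43 fell 2-fold by limma, nor did any probe set at an unadjusted p under 0.05. At an unadjusted p under 0.05, 966 probe sets were higher and 1197 lower. The count of 43 became 21 without EI-52 replicate 1, 19 without EI-52 replicate 2, 57 without EI-52 replicate 3, and 21, 16 and 23 without DMSO replicates 1, 2 and 3. The 57 without EI-52 replicate 3 held 27 of the 43. In all, 16 of the 43 calls, each of them a rise, passed whichever array was left out. The design text describes the treated and vehicle replicates as cultures of the cell line, while the labels do not say how independent they were. The p-values therefore measure the spread between these samples, which may be in part technical.

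**Figure D1:**
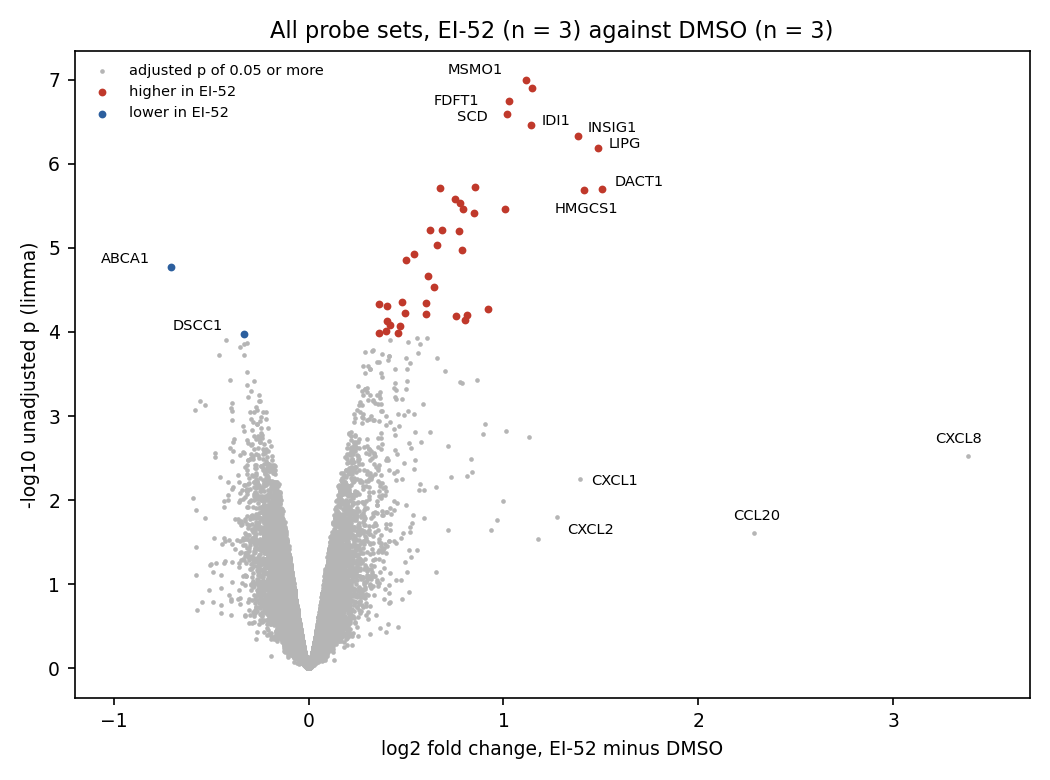
Each point is 1 of 19363 probe sets, with the log2 fold change (EI-52 minus DMSO) on the horizontal axis and −log10 of limma's unadjusted p on the vertical axis. The 41 higher probe sets reach 1.51 with DACT1, the 2 lower ones are ABCA1 and DSCC1, and the chemokine genes CXCL8 and CCL20 lie far to the right in grey, not past the adjusted threshold.

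Of the 22 measured genes of the cholesterol synthesis list, 17 rose, none fell, and all 22 had positive log2 fold changes with a median of 0.76. Adjusted over the list alone, all 22 were higher. The steepest rises included HMGCS1 (Entrez gene 3157, 5p12), INSIG1 (3638, 7q36) and IDI1 (3422, 10p15.3). INSIG1, a sterol-sensitive anchor that holds SREBP in the endoplasmic reticulum, rose by 1.38 ± 0.076 (adjusted p = 0.00151). IDI1, an isomerase that supplies building blocks for isoprenoids, rose by 1.14 ± 0.060 (adjusted p = 0.00136). MSMO1 (6307, 4q32-q34), a demethylase of late sterols, rose by 1.12 ± 0.049, and FDFT1 (2222, 8p23.1-p22), squalene synthase, by 1.03 ± 0.049. The adjusted p of each was 0.00116. FDFT1 signal went from 11.02 ± 0.024 (SD, n = 3) in DMSO to 12.05 ± 0.063 in EI-52.

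More members were chosen after their values were seen. STARD4, a cytosolic sterol carrier, rose by 0.85 ± 0.064. Along the pathway itself, SQLE, squalene epoxidase, rose by 0.79 ± 0.059, LSS, lanosterol synthase, by 0.68 ± 0.046, and DHCR7, which acts in the last steps, by 0.77 ± 0.063. The 5 members that did not pass were CYP51A1 (0.66, adjusted p = 0.0634), EBP (0.42, 0.0519), MVK (0.36, 0.0670), NSDHL (0.31, 0.201) and SREBF2 (0.26, 0.236). The list as a whole was shifted upward by camera with a preset correlation (adjusted p = 2.09e-53), with an adjusted p = 0.0719 with an estimated correlation. The count of 17 was 11, 13 and 13 without EI-52 replicates 1, 2 and 3. It was 14, 10 and 11 without DMSO replicates 1, 2 and 3, and 10 of the calls passed whichever array was left out. DHCR7 was lost without EI-52 replicate 1 and without DMSO replicate 2, with an adjusted p of at most 0.0636.

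**Figure D2:**
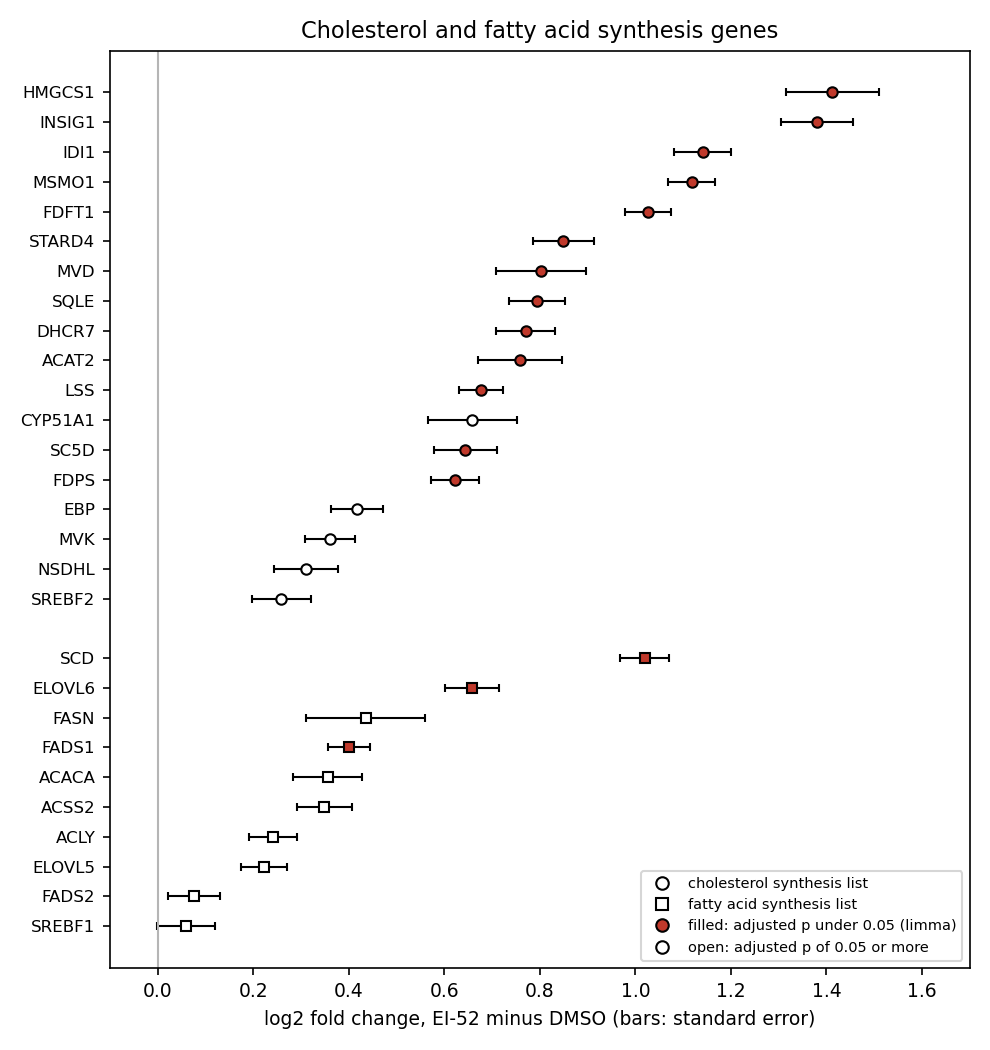
Log2 fold changes (EI-52 minus DMSO, horizontal axis) with standard errors for genes of the cholesterol (circles) and fatty acid (squares) lists, n = 3 per group, filled where limma's adjusted p was under 0.05. All values shown are above 0, from 0.059 for SREBF1 to 1.41 for HMGCS1.

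The fatty acid synthesis list had 3 of 10 measured genes higher and none lower, and 8 higher when adjusted over the list alone. SCD (6319, 10q24.31), which introduces the double bond of oleate, rose by 1.02 ± 0.051 (adjusted p = 0.00125), a 2.03-fold rise. ELOVL6, an elongase of long-chain fatty acids, rose by 0.66 ± 0.057 (adjusted p = 0.00897), and FADS1, a desaturase of polyunsaturated chains, by 0.40 ± 0.045 (adjusted p = 0.0321). FASN, which builds palmitate, gave 0.44 ± 0.12 (adjusted p = 0.294). SREBF1 gave 0.059 and FADS2 0.076. The list's median was 0.35, with a camera adjusted p = 2.88e-14 and an adjusted p = 0.0719 with an estimated correlation. SCD passed whichever array was left out. ELOVL6 had adjusted p of 0.0632, 0.0731 and 0.0744 without EI-52 replicate 1, EI-52 replicate 2 and DMSO replicate 2, and FADS1 had 0.0747 to 0.189 in all 6 such fits.

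ABCA1 (Entrez gene 19, 9q31.1), which pumps cholesterol and phospholipid out of the cell, fell by 0.70 ± 0.067 on the log2 scale (adjusted p = 0.0138). It was 1.63-fold lower in EI-52. Its signal was 6.52 ± 0.036 (SD, n = 3) in DMSO and 5.82 ± 0.12 in EI-52, and the groups did not overlap. The fall had adjusted p of 0.0731 to 0.114 when any array other than EI-52 replicate 3 was left out. LIPG (9388, 18q21.1), a secreted phospholipase that acts on lipoproteins, rose 2.80-fold by 1.49 ± 0.086 (adjusted p = 0.00181). Its DMSO signal of 5.55 ± 0.051 (SD, n = 3) was also below the lowest array median of 6.98, with no filter for background. Its rise passed whichever array was left out. LPIN1, a phosphatidate phosphatase chosen after its value was seen, rose by 0.61 ± 0.060 (adjusted p = 0.0170), with adjusted p up to 0.119 when an array other than EI-52 replicate 3 was left out.

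The largest rise past the adjusted threshold was that of DACT1 (51339, 14q23.1), an antagonist of WNT signalling, at 1.51 ± 0.10 (adjusted p = 0.00364), or 2.84-fold. Its DMSO signal of 5.72 ± 0.17 (SD, n = 3) lay below every array median, the lowest being 6.98, and no filter for background was applied. MACC1 (346389, 7p21.1), a gene linked to metastasis of colon cancer, rose by 1.01 ± 0.075 (adjusted p = 0.00450). DACT1 and MACC1 passed whichever array was left out. KRT20, a keratin of differentiated intestinal epithelium, rose by 0.92 ± 0.10 (adjusted p = 0.0333). Its adjusted p was 0.0568 to 0.184 in the 6 fits that leave out an array. It was the only 1 of 12 measured intestinal identity genes past the threshold over all genes, while over the list alone KRT20 was higher and VIL1, a brush border protein, lower at −0.40. That list had a median of 0.020 and a camera adjusted p = 0.0880. The DMSO signals of MACC1, KRT20 and VIL1, at 6.32, 5.92 and 4.73, also lay below every array median. Of the 43 calls, 21 belonged to no fixed list. Chosen from these after their values were seen, the transcription factor gene MEF2C rose by 0.85 ± 0.058 and FGFBP1, a carrier of fibroblast growth factors, by 0.78 ± 0.056. Both passed whichever array was left out.

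The mean of the list of NF-kB targets and chemokines spread widely between treated arrays, mostly through a few chemokine genes. No member of the 22 passed over all genes by limma, 9 had an unadjusted p under 0.05, and 7 were higher adjusted over the list alone. CXCL8, the neutrophil chemokine IL-8, gave 3.38 ± 0.75 (adjusted p = 0.211), with signals of 9.12, 8.66 and 5.98 in EI-52 replicates 1 to 3 against a DMSO mean of 4.53 ± 0.14 (SD, n = 3). RELB, an NF-kB subunit, gave 0.70 ± 0.10 (adjusted p = 0.0763). Chosen after their values were seen, the chemokine genes CCL20, CXCL1 and CXCL2 gave 2.29 ± 0.79, 1.39 ± 0.35 and 1.28 ± 0.40. The list's mean over its DMSO level was 0.81, 0.74 and 0.16 in EI-52 replicates 1, 2 and 3. The list was shifted upward by camera (median 0.18, mean 0.57, adjusted p = 1.01e-07), with an adjusted p = 0.391 with an estimated correlation. Without EI-52 replicate 3, 6 of its members passed, with CXCL8 at 4.35 (adjusted p = 0.00357), CXCL1 at 1.84 (0.0112) and RELB at 0.81 (0.0290).

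The list of targets of NRF2, the regulator of antioxidant genes, also had its lowest treated mean in EI-52 replicate 3. None of the 25 passed over all genes by limma, 10 had an unadjusted p under 0.05 (9 of them positive), and 9 were higher adjusted over the list alone. TXNRD1, thioredoxin reductase, gave 0.62 ± 0.12 (adjusted p = 0.172) and ME1, malic enzyme, 0.37 ± 0.062 (adjusted p = 0.113). The list's mean over DMSO was 0.35, 0.28 and 0.096 in EI-52 replicates 1, 2 and 3. Its median was 0.16 (camera adjusted p = 2.72e-07, and adjusted p = 0.391 with an estimated correlation), and 0.092 without EI-52 replicate 1 and 0.10 without DMSO replicate 3. Without EI-52 replicate 3, 6 members passed, among them TXNRD1 at 0.77 (adjusted p = 0.0102) and HMOX1, heme oxygenase, at 1.36 (0.0170). HMOX1 was chosen after its values were seen.

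**Figure D3:**
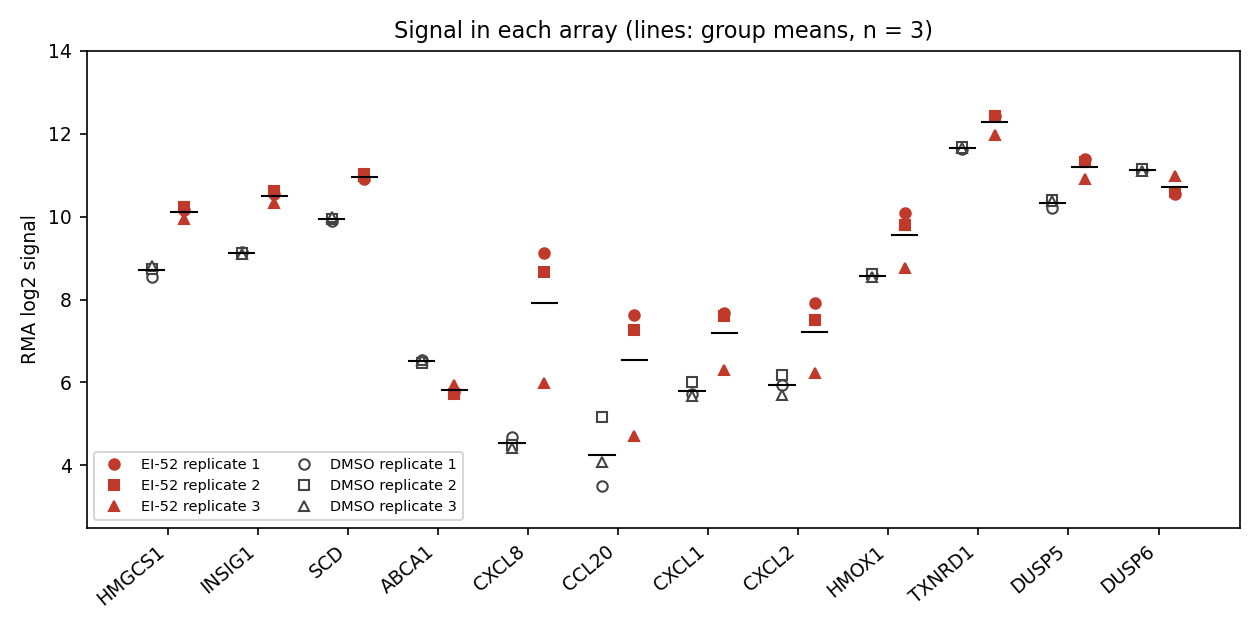
RMA log2 signal (vertical axis) of 12 genes in each of the 6 arrays, with DMSO open and EI-52 filled and a line at each group mean. HMGCS1, INSIG1 and SCD were high in all 3 EI-52 arrays, whereas CXCL8 stood at 9.12, 8.66 and 5.98 in EI-52 replicates 1, 2 and 3.

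Among 21 immediate early genes, NR4A2, a nuclear receptor induced by many stimuli, rose by 0.50 ± 0.046 (adjusted p = 0.0116), and no other member passed over all genes. The call of NR4A2 had adjusted p of 0.0938 without EI-52 replicate 2 and of 0.0894, 0.0833 and 0.0765 without DMSO replicates 1, 2 and 3. Adjusted over the list alone, 6 were higher, including JUND and JUN, and 2 lower, EGR1 and KLF10. The list's median was 0.12 (camera adjusted p = 0.000194, and adjusted p = 0.391 with an estimated correlation) and 0.068 without EI-52 replicate 1, 0.077 with array weights and 0.18 after centring on housekeeping genes. Genes for danger signals and immune ligands had a median of 0.085 over 17 members (camera adjusted p = 0.000543, and adjusted p = 0.391 with an estimated correlation), and the median was 0.056 without EI-52 replicate 2 and 0.15 after centring on housekeeping genes. No member passed over all genes by limma, 5 had an unadjusted p under 0.05, and 3 were higher adjusted over the list alone. These were MICA at 0.44 ± 0.070 and MICB at 0.44 ± 0.070, which encode ligands of the receptor NKG2D, and TNFSF9, chosen after its value was seen, at 0.29. The 26 hypoxia and glycolysis genes had a median of 0.046 (camera adjusted p = 0.00637, and adjusted p = 0.545 with an estimated correlation). The list's mean over DMSO was 0.0999, 0.093 and 0.0070 in EI-52 replicates 1, 2 and 3, and 0.022, 0.0098 and −0.032 in the DMSO arrays, so EI-52 replicate 3 lay below 2 of them. Without EI-52 replicate 1 the median was 0.024 with a camera adjusted p = 0.0601, without DMSO replicate 3 it was 0.023, and without DMSO replicate 1 it was 0.072. It was 0.074 by cyclic loess, 0.070 by quantile normalization and 0.11 after centring on housekeeping genes. None passed by limma and 6 had an unadjusted p under 0.05, the smallest in P4HA1 at 0.20 and ADM at 0.24.

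DNA replication, DNA repair and oxidative phosphorylation passed camera's threshold downward, with adjusted p = 0.391, 0.475 and 0.447 with an estimated correlation. After centring on housekeeping genes the replication median was −0.081, beside −0.14. All 32 measured replication genes had negative log2 fold changes, with none past limma's threshold over all genes, 18 at an unadjusted p under 0.05 and 14 lower adjusted over the list alone. CCNE2, a cyclin of the entry into S phase, gave −0.30 ± 0.062 (adjusted p = 0.197), and GINS2, part of the replicative helicase, −0.21 ± 0.047 (adjusted p = 0.217). The list had means over DMSO of −0.16, −0.13 and −0.15 in EI-52 replicates 1, 2 and 3. In DMSO replicates 1, 2 and 3 they were 0.047, 0.020 and −0.067. DSCC1 (79075, 8q24.12), which acts in clamp loading for sister chromatid cohesion and was in no list, fell by 0.33 ± 0.042 (adjusted p = 0.0479). Its adjusted p was 0.0935 to 0.265 in the 6 fits that leave out an array.

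Repair genes had a median of −0.093 over 26 members (camera adjusted p = 0.00224, and adjusted p = 0.475 with an estimated correlation). The median was −0.032 after centring on housekeeping genes. Without EI-52 replicate 1 it was −0.075 and camera's adjusted p was 0.0582. None passed by limma and 5 had an unadjusted p under 0.05, with RAD51AP1 at −0.31 and BRCA1 at −0.18 having the smallest p. The 29 oxidative phosphorylation genes had a median of −0.064 (camera adjusted p = 0.000358, and adjusted p = 0.447 with an estimated correlation), 27 of them negative. That median was −0.0025 after centring on housekeeping genes, −0.038 by cyclic loess and −0.041 by quantile normalization. None passed by limma and 2 had an unadjusted p under 0.05, NDUFA2 at −0.20 and NDUFS7 at −0.18. Mitosis genes had a median of −0.042 over 32 members, and the list missed camera's threshold (adjusted p = 0.0724). Its smallest p-values were those of NDC80 at −0.16 and BIRC5 at −0.15, and 5 members had an unadjusted p under 0.05.

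**Figure D4:**
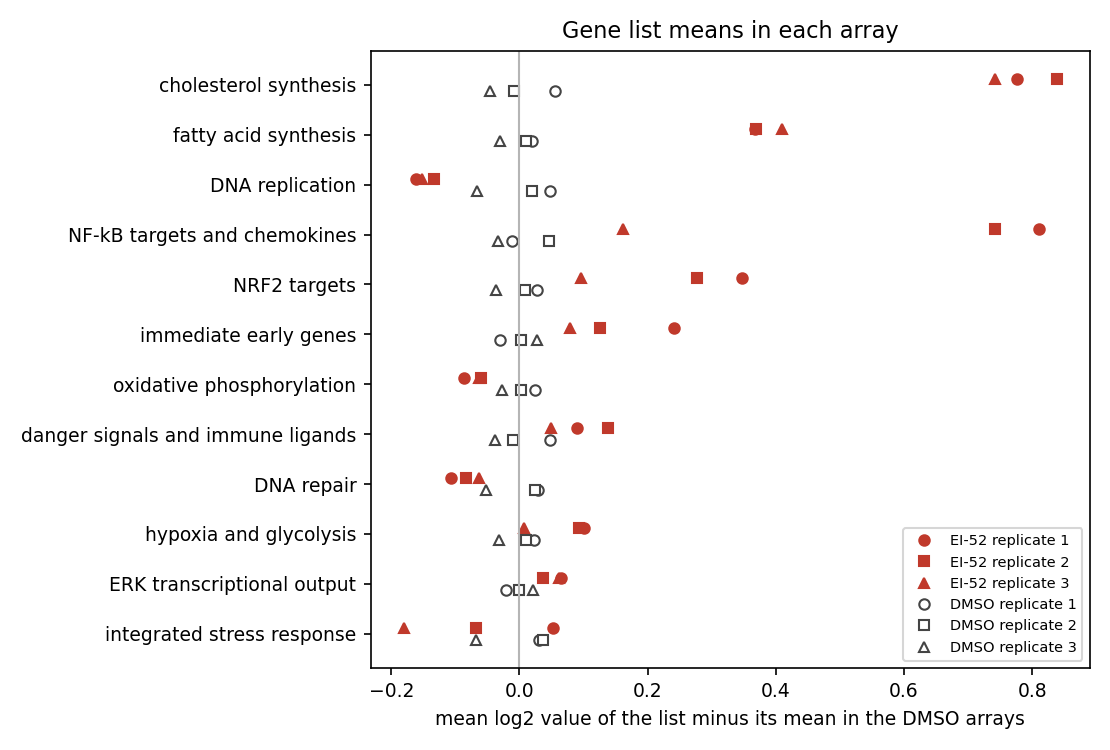
Mean log2 value of each gene list in each array minus its mean over the 3 DMSO arrays (horizontal axis), for the 10 lists past camera's threshold and for 2 lists that were not, ERK transcriptional output and integrated stress response. The 3 EI-52 arrays lie close together on cholesterol synthesis, at 0.78, 0.84 and 0.74, and spread from 0.16 to 0.81 on NF-kB targets and chemokines.

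The list of 19 genes that report ERK activity missed camera's threshold. It had 15 positive and 4 negative members, a median of 0.036 and a camera adjusted p = 0.0539, with no member past limma's threshold over all genes and 6 at an unadjusted p under 0.05. Camera's adjusted p was 0.0468 without EI-52 replicate 2 and 0.0060 without DMSO replicate 3. Adjusted over the list alone, DUSP5 and MYC were higher, at 0.86 ± 0.13 and 0.27 ± 0.050. DUSP6, a phosphatase that ERK signalling induces, and EGR1 were lower, at −0.41 ± 0.11 and −0.34 ± 0.091. Over all genes the adjusted p was 0.0904 for DUSP5, 0.139 for MYC, 0.282 for DUSP6 and 0.275 for EGR1, which was chosen after its value was seen. Without EI-52 replicate 3, DUSP5 passed at 1.02 (adjusted p = 0.0231) and DUSP6 at −0.55 (adjusted p = 0.0279). MAPK3, which encodes ERK1, gave −0.0017 ± 0.048, and MYD88 gave −0.026 ± 0.051. The 24 components of the RAS-ERK and TLR-MYD88 pathways had a median of −0.00023, a mean of 0.011 and an upward camera direction (adjusted p = 0.630). None of them passed by limma or had an unadjusted p under 0.05, and ARAF at 0.16 and IRAK1 at −0.099 had the smallest p.

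The integrated stress response list did not pass camera's threshold. Its 21 genes had a median of 0.0082, a mean of −0.065 and a downward camera direction (adjusted p = 0.953). ATF4 was not analysed here. None passed by limma over all genes and 9 had an unadjusted p under 0.05. Adjusted over the list alone, CTH was higher at 0.24 ± 0.049, and DDIT3, FGF21 and STC2 were lower. DDIT3, which encodes the stress factor CHOP, gave −0.59 ± 0.17 (adjusted p = 0.289), FGF21 gave −0.23 ± 0.055, and STC2, chosen after its value was seen, −0.26 ± 0.068. HSPA5, the main chaperone of the endoplasmic reticulum, gave −0.016 ± 0.061. The 26 genes of ER chaperones and ER-associated degradation had a median of −0.024 (camera adjusted p = 0.253). None passed by limma and 3 had an unadjusted p under 0.05, with HERPUD1 at −0.31 and PDIA4 at −0.15 having the smallest p. Neighbouring lists had medians near 0. They were −0.018 (mean 0.0011, with a downward camera direction) for 21 genes of amino acid synthesis and transport (camera adjusted p = 0.953), −0.027 for 20 cytosolic tRNA synthetases (0.953) and −0.017 for 17 genes of eIF2 kinases and translation control (0.953). They were 0.0078 for 18 heat shock genes (0.168) and −0.015 for 10 mitochondrial chaperones and proteases (0.953). HSPD1 and HSPE1, written into both of these lists, and HSPB1 of the heat shock list were not measured. By limma no measured member of the neighbouring lists passed, and 1, 0, 1, 3 and 0 in that order had an unadjusted p under 0.05. The smallest p-values belonged to ALDH18A1 at −0.16 and ASNS at 0.23, FARSB at −0.088 and FARSA at −0.079, EIF2AK3 at 0.15 and EIF2AK2 at 0.11, HSPB8 at 0.59 and HSPA1A at 0.21, and CLPP at −0.11 and CLPX at 0.040.

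The lists of p53 targets, BCL2 family, death receptor signalling, interferon-stimulated genes and antigen processing did not pass camera's threshold. The 27 p53 targets had a median of 0.041 (camera adjusted p = 0.130), with TP53INP1 at 0.23 higher adjusted over the list alone and CDKN1A, the p21 gene, at 0.18 ± 0.045 (adjusted p = 0.264). Medians were 0.0345 for 15 BCL2 family genes (camera adjusted p = 0.158), of which BIK at 0.36 was higher adjusted over the list alone and BCL2L1 gave 0.13, and 0.043 for 19 genes of death receptor signalling (0.115), with CFLAR at 0.18 and TNF at 0.16. They were 0.034 for 20 interferon-stimulated genes (0.0748), with RIGI at 0.25, and 0.060 for 15 genes of antigen processing and presentation (0.0782), with TAP1 at 0.15 and TAP2 at 0.097. By limma no member of these lists passed over all genes, and 4, 2, 2, 6 and 1 in that order had an unadjusted p under 0.05.

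Nor did the lists of sphingolipid metabolism, autophagy and lysosome, WNT targets, proteasome, ribosome biogenesis, ribosomal proteins and metallothioneins. The 24 sphingolipid genes had a median of 0.0098 (camera adjusted p = 0.168). Over that list alone, UGCG, glucosylceramide synthase, was higher at 0.32 ± 0.046, SGMS2, a sphingomyelin synthase, higher at 0.40 ± 0.076, and SPHK1, chosen after its value was seen, lower at −0.32. The 20 autophagy and lysosome genes had a median of −0.0038, a mean of −0.00077 and an upward camera direction (adjusted p = 0.953), with CTSB at −0.26 lower over the list alone and SQSTM1 at 0.32. The 15 WNT targets had a median of −0.039 (camera adjusted p = 0.953), with MYC higher over the list alone and AXIN2 at −0.22. Medians were 0.022 for 29 proteasome genes (camera adjusted p = 0.158), −0.017 for 25 ribosome biogenesis genes (0.953), −0.011 for 20 cytosolic ribosomal proteins (0.953) and 0.033 for 6 metallothioneins and zinc exporters (0.532). The ribosomal protein list was written with 39 genes and the metallothionein list with 9, so these medians cover only their measured part. By limma none of these 7 lists had a member past the threshold over all genes, and 4, 3, 5, 1, 2, 0 and 0 in that order had an unadjusted p under 0.05. The smallest p-values in the last 4 belonged to PSMD2 at −0.11 and PSMD13 at 0.13, PPAN at 0.25 and GNL3 at −0.10, RPL15 at −0.062 and RPL3 at 0.047, and MT1M at 0.10 and MT1F at 0.055.

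Lists of markers of cell types that HCT116 cultures should lack did not pass camera's threshold. The medians were −0.026 for 10 fibroblast markers (camera adjusted p = 0.835), −0.018 for 6 endothelial markers (0.971) and 0.010 for 11 leukocyte and blood cell markers (0.953, with a mean of −0.054 and a downward camera direction). By limma none of their members passed, and 2, 1 and 4 had an unadjusted p under 0.05. The smallest p-values belonged to PDGFRA at −0.16 and COL1A1 at 0.12, KDR at 0.15 and CDH5 at −0.20, and NKG7 at −0.22 and ITGAM at 0.23. The 10 housekeeping genes had a median of −0.024 (camera adjusted p = 0.168), with IPO8 at −0.16. PPIA at −0.20 ± 0.047 was lower over that list alone, while none passed over all genes by limma and 2 had an unadjusted p under 0.05.

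Across the 37 lists, 10 passed camera's threshold with the preset correlation, 7 higher and 3 lower. With an estimated correlation none passed, though 3 had an unadjusted p under 0.05. By fry's test for a shift in 1 direction, 2 passed, cholesterol synthesis and fatty acid synthesis, both with an adjusted p = 0.000867. Fry's mixed test asks instead whether members differ in either direction. Lists that missed camera's threshold passed it, among them p53 targets (adjusted p = 6.76e-05) and sphingolipid metabolism (0.000702). So did housekeeping genes (0.00966), fibroblast markers (0.0384) and leukocyte and blood cell markers (0.0468). Passing the mixed test therefore does not single out a pathway. The RAS-ERK and TLR-MYD88 pathway components did not pass it (0.754).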

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

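The count at an unadjusted p was chosen after seeing the data, and all other tests in this part were planned. No called result changed direction under any alternative, and for the changes below the cause was not tested unless a reason is given. Main values were 43 probe sets past the threshold, 41 higher and 2 lower, 10 of them at least 2-fold, and 10 lists.

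Another scaling gave 4 lower probe sets after centring on the array median, 5 lower after cyclic loess, and 84 in all with 82 higher after centring on housekeeping genes. That last choice moved the median of all probe sets from −0.015 to 0.046 by construction. The share of calls that were higher stayed between 91.7% and 97.6% under the 4 scalings, beside 95.3%. The filter at the median signal gave 160 calls, 125 higher and 35 lower. An intensity trend in the variance prior gave 137, with 110 higher and 27 lower. The robust prior gave 1 lower. Array weights gave 74, with 65 higher and 9 lower. An adjusted p under 0.01 gave 21, all 21 higher and 0 lower, treat against 1.5-fold gave 4, and an unadjusted p under 0.05 gave 2163. Stricter thresholds give fewer by construction.

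With the replicate block, 7 passed, 7 higher and 0 lower, 5 of them in the cholesterol list (17 without it). Deviations of same-numbered arrays correlated at −0.0090, −0.011 and 0.047, and in 1 of 3 pairs the array correlated best with its own number. The numbers therefore gave no hint of pairing.

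Leaving out 1 array gave 16 to 57 calls, 16 to 52 higher, 0 to 5 lower, and 7 to 19 at least 2-fold, where fewer arrays lower the power. Only leaving out EI-52 replicate 3 raised the count. That fit kept 27 of the 43 main calls, and 13 cholesterol genes passed in it, beside 17. List medians across these fits were −0.11 to −0.075 for DNA repair (adjusted p = 0.0582 without EI-52 replicate 1) and 0.023 to 0.072 for hypoxia and glycolysis (adjusted p = 0.0601 without EI-52 replicate 1). Without EI-52 replicate 1 the hypoxia median was 0.024.

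The estimated correlation left 0 lists and fry left 2, while the medians stay as they are by construction. By estimated correlation and by fry, the adjusted p was 0.391 and 0.117 for NRF2 targets (median 0.16), 0.391 and 0.117 for immediate early genes (0.12), and 0.391 and 0.173 for NF-kB targets (0.18). It was 0.391 and 0.0980 for danger signals (0.085), 0.391 and 0.0797 for DNA replication (−0.14), and 0.475 and 0.117 for DNA repair (−0.093). It was 0.545 and 0.395 for hypoxia and glycolysis (0.046), and 0.447 and 0.0980 for oxidative phosphorylation (−0.064). Cholesterol synthesis (0.76) and fatty acid synthesis (0.35) had 0.0719 by estimated correlation.

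Other settings gave 8 to 14 lists. Averaging the probe sets of a gene gave no value, since each gene had 1. Genes and lists outside these counts kept their direction where called: 185 of 196 were unchanged and 11 gained a call with array weights, and 160 were unchanged and 36 lost one with the replicate block. Signal near background limits dim genes, and the filter at the median signal left 32 of the 43 calls testable and kept all 32.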

Other observations

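Some genes of sterol handling lay outside the lists and were chosen after their values were seen. NPC1, which exports cholesterol from lysosomes, gave 0.36 ± 0.094 (limma adjusted p = 0.264), and TMEM97, a sterol-binding partner of NPC1, gave 0.32 ± 0.044 (adjusted p = 0.0601). ABCG1, an exporter like ABCA1, gave −0.33 ± 0.044 (adjusted p = 0.0531). It passed under array weights (adjusted p = 0.0395), centring on the array median (0.0477) and cyclic loess (0.0492). With an intensity trend in the variance prior it did not pass. Its DMSO signal of 5.66 ± 0.033 (SD, n = 3) lay below every array median, the lowest being 6.98, with no filter for background.

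With an intensity trend in the variance prior, 27 probe sets were lower. Chosen after their values were seen, they included ID1 and ID3, which restrain differentiation factors, at −0.28 (adjusted p = 0.00172) and −0.33 (0.00584). DEPTOR, which binds mTOR, gave −0.56 (0.0385), and FOXC1, a forkhead factor, −0.46 (0.00929).

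Tests for bias with signal level, scaling, a shift of all probe sets and a weaker response of EI-52 replicate 3 were chosen after the result was seen. Tests of lysosomal genes, LXR targets and other splits were written before they were run. The lysosomal and LXR tests address the rise of cholesterol genes and use lists outside the fixed ones, so they followed that result.

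The first pattern is the rise of cholesterol genes, with a median of 0.76. The tables argue against a bias with signal level, since the highest median of 10000 random lists of like signal was 0.057. The lowest median of the cholesterol list under the 4 scalings was 0.76. Those scalings moved the median of all probe sets only from −0.015 to between −0.021 and 0.046. They could hardly have lowered 0.76, so they do not decide on scaling. The deposited median of −0.015 shows no shift of all probe sets near 0.76. Lysosomal trapping and lower LXR activity stay open: the means were −0.010 over 21 lysosomal genes and −0.011 over 10 LXR targets other than ABCA1. Bounds on these means, set before the means were computed, were met but were the wrong test. Members went both ways (CTSB −0.26 and NPC1 0.36, ABCG1 −0.33 and PLTP 0.33), and the called ABCA1 was left out. A response to treatment also stays open, and no mechanism was tested.

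The second pattern is the split of the NF-kB list's mean between EI-52 arrays, mostly through a few chemokine genes. The rise of cholesterol genes in EI-52 replicate 3 was 91.8% of that in the other EI-52 arrays. The share was 20.7% for NF-kB targets, 30.9% for NRF2 targets and 111% for fatty acid genes. These shares argue against a response of replicate 3 that was weaker by a like share on all lists. A weaker exposure to which lists respond unequally stays open, since these shares cannot tell it apart. The difference between EI-52 replicates 1 and 2 and replicate 3 was at least 0.60 under the 4 scalings, beside 0.62 as deposited. Medians of EI-52 arrays 1, 2 and 3 were 7.03, 7.02 and 7.02, so these scalings had little to move and do not decide on scaling. Those medians show no shift of a whole array near 0.62. Differences in handling between samples stay open and were not tested.

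The third pattern is the excess of rises, 41 against 2. The 4 other scalings moved the median of all probe sets from −0.015 to between −0.021 and 0.046. They left 44 higher and 4 lower, 57 and 5, 47 and 3, and 82 and 2, at least 91.7% higher. Such moves are small beside the smallest called absolute log2 fold change of 0.33, so they could hardly have changed the balance. They therefore do not decide whether a shift of all probe sets from scaling adds to the excess. The deposited median of −0.015 shows no upward shift. The excess depends on the threshold, with 966 higher and 1197 lower at limma's unadjusted p under 0.05. A change of all transcripts alike stays open, since RMA would remove it. For the count itself, 1 of 10 splits of the arrays, the real one with 43, gave as many, and the highest of the others gave 0. The other 9 had 514 to 1655 probe sets at an unadjusted p under 0.05, beside 2163, and 10 splits are too few for a share under 0.05.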
